A study of Homo sapiens with 12 samples.

How the data were processed

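RNA from the mantle cell lymphoma line Z-138 was profiled in 12 libraries that form 4 groups of 3 replicates. The cells carried a control shRNA or an shRNA against SMARCA4, were grown with doxycycline, and received either DMSO or 3 µM ibrutinib plus 3 µM venetoclax. Per the labels, RNA was isolated with a Qiagen RNeasy kit and libraries were made with the Lexogen QuantSeq kit, which reads the 3' ends of mRNA. The submitters' processing notes name bcl2fastq 2.17.1.14, HISAT2, HTSeq and the genome build hg19. The versions of HISAT2 and HTSeq, the annotation release, the strand setting and any filter on the table are not given in the sources used here.

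The authors deposited 1 table of gene counts, whole numbers with no normalization, for 13820 genes in the 12 libraries. The lowest total of any gene in it was 13 counts. Of its rows, 1656 had an Ensembl identifier and no symbol and are referred to by identifier. Columns were matched to samples by name. In 11 columns the name gave the shRNA, the treatment and the replicate number. The remaining column named the control shRNA and replicate 1 but no treatment, and it was taken as control_IbrVen replicate 1, the only sample that no other column named. This assignment was made by names alone, so counts and some calls without that library are given. On the second principal component of log2 CPM it lay at -12.7. The other control libraries under drug lay at -12.8 and -11.3, and the control DMSO libraries at 12.1, 11.0 and 13.0.

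No genome positions are given, because the reference annotation at hand (GENCODE release 29, GRCh38) is of another build than the authors' hg19. Gene types from it were matched by Ensembl identifier for 12270 of the 12602 genes tested (97.4%). No single-sample share is reported, so no binomial intervals were needed. Standard errors cover the spread between libraries. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries alone.

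Genes were kept by edgeR's filterByExpr with the 4 groups (minimum count 10, minimum total 15), which left 12602 and removed 1218. Counts were scaled by the trimmed mean of M values (TMM). All 12 libraries entered a quasi-likelihood model with 1 coefficient per group in edgeR 4.0.16 under R 4.3.3. It had 8 residual and 22.5 prior degrees of freedom, and the biological coefficient of variation was 5.69%. There were 5 comparisons: knockdown in DMSO, knockdown under drug, drug in control cells, drug in knockdown cells, and the interaction, which is the drug effect in knockdown cells minus that in control cells. Quasi-likelihood F tests, which are two-sided, were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. "Rose" and "fell" are used for genes and lists past it. The standard error (SE) of a log2 fold change is its size divided by the square root of F and is approximate, as are the 95% intervals of the interaction.

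The following were chosen before the data were examined: the tests, the alternatives except 7 named below, 28 gene lists, and the rule for naming genes. Each list was tested with limma 3.58.1's camera on log2 CPM (counts scaled to a common library size, prior count 2) with a preset correlation of 0.01, and adjusted over the lists within a comparison. The camera test compares a list with all other genes. It was repeated with the correlation estimated per list, and with fry, which tests whether a list's own genes move on balance in 1 direction. A list is termed called by camera with the preset correlation alone. Of the 28 lists, 27 had at least 3 genes tested. The list of monocyte and macrophage markers had 0 and has no test. Member counts are given over all genes tested and adjusted over the list alone.

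Genes were named by rule. The rule takes SMARCA4, ATF3 and the tested members of the BCL2 family lists in every comparison. It adds the 10 largest changes in each direction among genes past the threshold with a mean log2 CPM of at least 3 and no overlap between the 3 and 3 libraries compared, a condition that 10% of unchanged genes meet by chance. It also adds up to 4 members per list with the smallest adjusted p, and all genes past the threshold where a comparison has fewer than 4. BTK, the single drug effects of RNA18S5, RNA28S5 and NEAT1, the FOS levels and the GAPDH counts were named after their values were seen. Some genes that the rule names are not reported here.

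Alternatives were DESeq2 size factors (RLE), library totals without scaling factors, no low-count filter, a filter at 5 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, fits of the 2 groups alone (not for the interaction), the replicate number as a block, a 2-fold minimum change, and leaving out each library. After seeing the data, 7 were added: taking out 5 ribosomal RNA rows, the same with library totals as scaling (for the interaction), thinning the deepest library to the median of the other 11, leaving out each library for the correlation between the drug responses and for that between the knockdown responses, and, for knockdown in DMSO, the replicate number as a block in the DMSO libraries alone, with and without the thinning. That block was added because the numbers pair these libraries when each 2 groups are judged apart, which was done only after the block over all libraries had been run: over 4423 genes with a mean log2 CPM of at least 5, the deviations from the group means correlated at 0.124, 0.134 and 0.261 for the 3 same-number pairs of control and knockdown DMSO libraries, each over 0.1, and at -0.206 to 0.108 for the 6 pairs with different numbers. The pairing comes from the data, since the labels do not say what a number marks.

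The model was tested on simulated data of the same size (12602 genes, 50 changed at each fold). In the knockdown comparison it recovered 54% of genes changed 1.25-fold, 60% at 1.5-fold, 88% at 2-fold and 98% at 4-fold, with 10 false calls among 160. For the drug in control cells it recovered 24%, 58%, 82% and 98% at those folds, with 11 false calls among 142. For the interaction it recovered 12%, 54%, 66% and 92%, with 10 false calls among 122. Each run changed its own random draw of genes. At 2-fold, edgeR recovered 82.5%, limma-voom 83.5% and DESeq2 78% of 200 changed genes. A simulated list of 30 genes changed 1.25-fold was called, and 0 of 50 unchanged lists were. Simulated genes were drawn independently, so this does not test list calls among correlated genes. The estimated correlation was 0.478 for the mitochondrially encoded list.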

Results

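Z-138, an established mantle cell lymphoma line, was studied with and without knockdown of SMARCA4, a core ATPase of the SWI/SNF chromatin remodelling complex. Cells received DMSO or the combination of ibrutinib, an inhibitor of the B cell receptor kinase BTK, and venetoclax, an inhibitor of the survival protein BCL2. Total counts in the control DMSO libraries were 10151679, 8307729 and 8480698. The knockdown DMSO libraries had 9159780, 9086910 and 22528537 counts, the last being the deepest of all. Control libraries under drug had 8732642, 7905971 and 8632355 counts, and knockdown libraries under drug 7279503, 8217130 and 8896669. The first principal component of log2 CPM held 55.0% of the variance and separated the shRNAs, and the second held 7.77% and separated drug from DMSO. Ribosomal 18S and 28S RNA took 9.15% ± 0.308 (SD, n = 3) of counts in control DMSO libraries and 10.5% ± 0.525 in knockdown DMSO libraries. Under drug it took 10.6% ± 0.330 in control and 8.36% ± 1.01 in knockdown libraries.

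SMARCA4 (ENSG00000127616) was measured first, to check the knockdown. Its level was 577 ± 21.6 CPM (SD, n = 3) with the control shRNA and 170 ± 9.67 CPM with the SMARCA4 shRNA in DMSO. Under drug the levels were 610 ± 28.2 and 175 ± 8.66 CPM. SMARCA4 fell by 1.77 on the log2 scale (SE 0.06, adjusted p = 1.99e-21) in DMSO, which left 29.4% of the control level. It fell by 1.80 (SE 0.06, adjusted p = 1.96e-21) under drug, which left 28.7%. All 3 knockdown libraries lay below all 3 control libraries in both treatments. The drug changed SMARCA4 by 0.08 (SE 0.05, adjusted p = 0.686) in control cells and 0.05 (SE 0.06, adjusted p = 0.880) in knockdown cells, neither past the threshold.

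**Figure D1:**
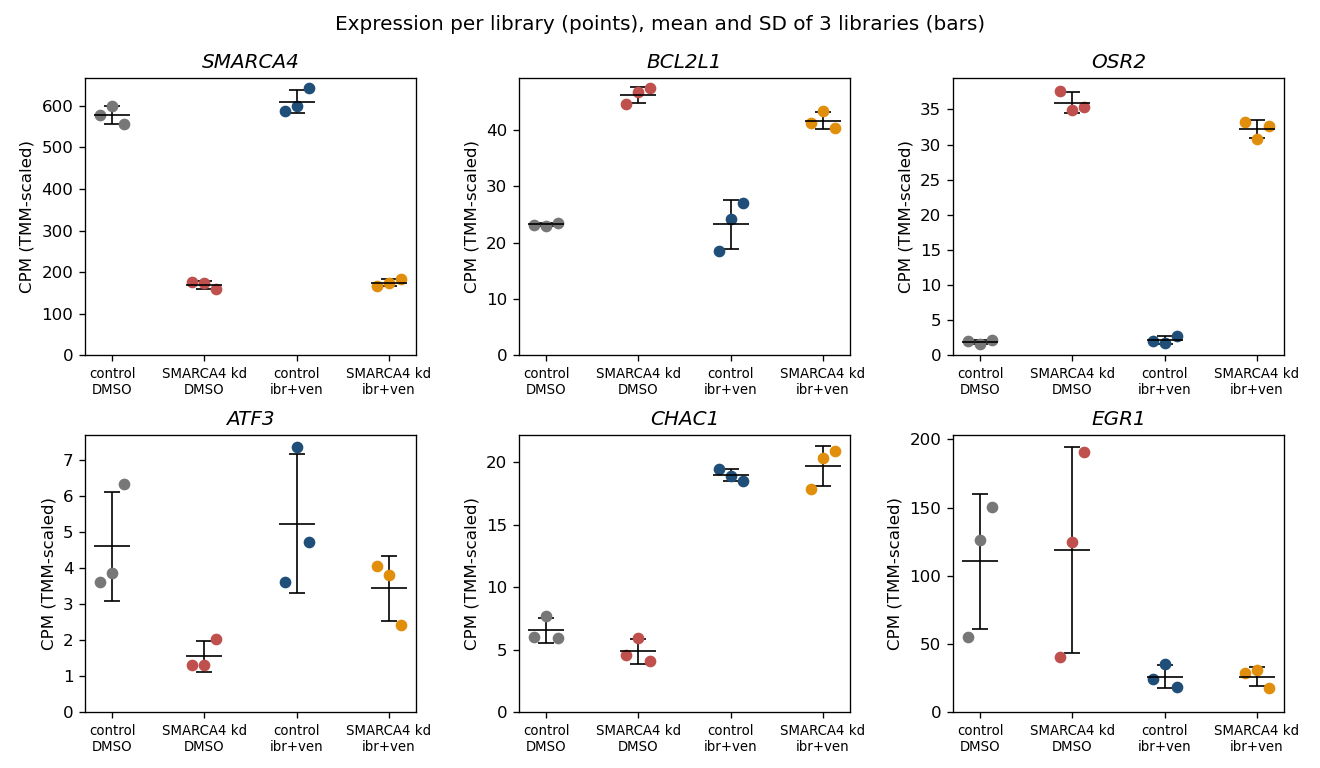
TMM-scaled CPM of SMARCA4, BCL2L1, OSR2, ATF3, CHAC1 and EGR1 in each of the 12 libraries (points), with the mean and SD of the 3 libraries of each group (bars). SMARCA4, BCL2L1 and OSR2 separate by shRNA, and CHAC1 and EGR1 separate by drug.

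Knockdown in DMSO compares the SMARCA4 shRNA with the control shRNA without drug. In every library the knockdown goes with its construct, so effects of SMARCA4 loss cannot be told apart from other effects of the construct. GYPC, which encodes glycophorin C, fell by 3.92 on the log2 scale (SE 0.14, adjusted p = 1.56e-20). S100A4, a calcium-binding protein, fell by 3.02 (SE 0.08), and TNFRSF1B, which encodes TNF receptor 2, fell by 2.86 (SE 0.09). The transcription factor gene OSR2 rose by 4.19 (SE 0.14), the cannabinoid receptor gene CNR1 by 3.20 (SE 0.12), the cortactin gene CTTN by 2.24 (SE 0.07) and SDC1, which encodes the plasma cell marker CD138, by 1.96 (SE 0.11). The row of the microRNA gene MIR30A rose by 3.13 (SE 0.11). For each of these genes the 3 knockdown libraries did not overlap the 3 control libraries. In all, 3940 of 12602 genes passed the threshold, 1899 higher and 2041 lower, of which 325 rose and 431 fell by at least 2-fold.

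B cell identity and B cell receptor genes fell as a list in DMSO. Of 21 members tested, 12 fell, 1 rose and 8 did not pass, with the same counts adjusted over the list alone (12 lower, 1 higher; camera adjusted p = 2.89e-06, and adjusted p = 0.0182 with an estimated correlation). MS4A1, which encodes CD20, fell by 1.36 (SE 0.06), the PI3-kinase delta gene PIK3CD fell by 0.88 (SE 0.05) and VPREB3 fell by 1.85 (SE 0.16). BTK, the target of ibrutinib, fell by 0.79 (SE 0.08, adjusted p = 1.59e-09), a gene singled out after its value was seen. Markers of T and NK cells moved in the same direction: all 3 tested members (CD3G, CD4 and PRF1) fell, all 3 also adjusted over the list alone (camera adjusted p = 0.00551, and adjusted p = 0.0721 with an estimated correlation). PRF1 lost its call without control_DMSO replicate 2 (-1.62, adjusted p = 0.0698). CD3G had 129 to 162 counts per control library and 12 to 35 per knockdown library. The fibroblast and epithelial markers gave no list call (camera adjusted p = 0.159), and 1 of 3 members, COL1A1, fell by 0.50 (SE 0.10), with 2 lower adjusted over the list alone. With fry this list moved lower (adjusted p = 0.000292).

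The G2/M and mitosis, MYC and ribosome biogenesis, and heat shock lists were called lower in DMSO, while the G1/S and DNA replication list was not called (camera adjusted p = 0.0614). Of 28 G2/M and mitosis genes, 15 fell and 1 rose (16 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000199, and adjusted p = 0.0192 with an estimated correlation). The mitotic kinases AURKA and PLK1 had log2 fold changes of -0.57 (SE 0.06) and -0.70 (SE 0.08). Of 25 MYC and ribosome biogenesis genes, 18 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 3.56e-06, but adjusted p = 0.0674 with an estimated correlation), among them NOP16 and NOP56 with log2 fold changes of -0.45 (SE 0.06) and -0.41 (SE 0.06). Of 16 heat shock genes, a list chosen as cytosolic that also holds the mitochondrial chaperonin genes HSPD1 and HSPE1, 12 fell and 1 rose (13 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000199, but adjusted p = 0.0670 with an estimated correlation), among them HSPD1 and HSPE1 with -0.40 (SE 0.05) each, HSP90AA1 with -0.31 (SE 0.05) and HSPA8 with -0.29 (SE 0.05).

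Metabolic genes changed in both directions in DMSO. Of 26 glycolysis and hypoxia genes, 16 fell and 4 rose (17 lower and 4 higher adjusted over the list alone; camera adjusted p = 0.00209, but adjusted p = 0.119 with an estimated correlation). The row of GAPDH, a member, held few counts: 25 to 30 per control and 29 to 77 per knockdown library in DMSO. Under drug it held 44 to 57 and 21 to 26. Why this row is so low was not tested. The pyruvate kinase gene PKM fell by 0.86 (SE 0.06) and the lactate transporter gene SLC16A3 fell by 2.10 (SE 0.18), while ADM, which encodes adrenomedullin, rose by 1.74 (SE 0.12). Of 30 nuclear oxidative phosphorylation genes, 14 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.000776, but adjusted p = 0.232 with an estimated correlation), among them NDUFA9 with -0.40 (SE 0.05). Of 27 cholesterol and fatty acid synthesis genes, 12 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0230, but adjusted p = 0.154 with an estimated correlation). The cholesterol enzyme genes SQLE and DHCR7 rose by 0.74 (SE 0.09) and 0.93 (SE 0.14), while the fatty acid desaturase genes FADS1 and FADS2 had -1.62 (SE 0.11) and -3.00 (SE 0.25).

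Among BCL2 family genes in DMSO, BCL2L1 (ENSG00000171552), which encodes the survival protein BCL-XL, went from 23.2 ± 0.285 to 46.2 ± 1.42 CPM (SD, n = 3). It rose by 0.996 on the log2 scale (SE 0.09, adjusted p = 3.70e-10), with all 3 knockdown libraries above all 3 control libraries. It was the 1 survival member of 4 tested that passed over all genes (2 higher adjusted over the list alone). The survival genes BCL2A1 and BCL2L10 and the death genes BCL2L11 and BOK had no row under those symbols and were not tested. BCL2 itself had a log2 fold change of -0.03 (SE 0.08, adjusted p = 0.831). MCL1 missed the threshold (adjusted p = 0.0585) and passed it in 9 of 19 alternatives. These include the fit with the replicate number as a block in the DMSO libraries, added after the data were seen (0.15, adjusted p = 0.0181), and the fits without control_DMSO replicate 3 (0.25, adjusted p = 0.00282) and without SMARCA4kd_DMSO replicate 1 (0.21, adjusted p = 0.0233). Of 9 death members, 3 rose and 0 fell, also adjusted over the list alone, among them BBC3, which encodes PUMA, by 0.48 (SE 0.08) and BAD by 0.62 (SE 0.12). Neither list was called (camera adjusted p = 0.359 for survival and 0.127 for death members). With fry, which does not compare a list with all other genes, both moved higher (adjusted p = 0.00793 for survival and 2.03e-05 for death members). The stress-response transcription factor gene ATF3 (ENSG00000162772) went from 4.60 ± 1.503 to 1.55 ± 0.423 CPM (SD, n = 3) and fell by 1.44 (SE 0.29, adjusted p = 0.000266).

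Knockdown under drug asks how the shRNAs differ while both populations are treated. GYPC fell by 4.04 (SE 0.15) and S100A4 fell by 3.35 (SE 0.09), while OSR2 rose by 3.87 (SE 0.15), CNR1 by 3.19 (SE 0.12), CTTN by 2.44 (SE 0.07) and MIR30A by 2.97 (SE 0.11), with no overlap between the libraries compared. BCL2L1 rose by 0.84 (SE 0.10, adjusted p = 4.24e-08), again with all 3 knockdown libraries above all 3 control libraries. BCL2 had -0.02 (SE 0.09, adjusted p = 0.881). ATF3 had -0.61 (SE 0.28, adjusted p = 0.101), and without control_IbrVen replicate 1 it passed the threshold at -0.82 (adjusted p = 0.0351). In all, 3919 genes passed, 1860 higher and 2059 lower, of which 348 rose and 459 fell by at least 2-fold. With library totals alone the split was 2691 higher and 1447 lower.

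All 8 lists called in DMSO were also called under drug. B cell identity genes had 12 lower and 1 higher of 21 (13 lower and 1 higher adjusted over the list alone; camera adjusted p = 2.56e-06, and adjusted p = 0.0191 with an estimated correlation), and BTK fell by 0.92 (SE 0.09). T and NK cell markers had 2 of 3 lower, also adjusted over the list alone (camera adjusted p = 0.00727, but adjusted p = 0.0789 with an estimated correlation). MYC and ribosome biogenesis genes had 15 of 25 lower (19 adjusted over the list alone; camera adjusted p = 2.56e-06), glycolysis and hypoxia genes 15 of 26 lower and 3 higher (17 and 3; 0.00181), heat shock genes 9 of 16 lower (11; 0.00323), and cholesterol and fatty acid synthesis genes 15 of 27 higher and 2 lower (15 and 2; 0.00323). Each of these 4 lists had adjusted p = 0.0789 with an estimated correlation. G2/M genes had 14 of 28 lower and 1 higher (15 and 1 adjusted over the list alone; camera adjusted p = 0.00323, but adjusted p = 0.0695 with an estimated correlation).

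Mitochondrial and ribosomal protein genes under drug were called with the preset correlation and not with an estimated one. Of 13 mitochondrially encoded genes, 6 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.00541, but adjusted p = 0.386 with an estimated correlation), among them MT-ND6 with -0.86 (SE 0.06) and MT-ND5 with -0.55 (SE 0.05). Of 30 nuclear oxidative phosphorylation genes, 11 fell and 0 rose (13 and 0 adjusted over the list alone; camera adjusted p = 0.00727, but adjusted p = 0.345 with an estimated correlation). Of 32 cytosolic ribosomal proteins, 11 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 0.0377, but adjusted p = 0.594 with an estimated correlation), among them RPL37 by 0.27 (SE 0.05). The ribosomal protein call ended without control_IbrVen replicate 1, control_IbrVen replicate 2 or SMARCA4kd_IbrVen replicate 2, with adjusted p of up to 0.168. These groups sit in the comparison with the lower share of 18S and 28S RNA in knockdown than in control libraries (8.36% against 10.6%).

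The knockdown responses in DMSO and under drug, which share no libraries, correlated across 12602 genes at Pearson r = 0.861 and Spearman's coefficient 0.735. Genes are not independent replicates, so no p is given. Of the genes past both thresholds, 1354 rose in both where 280 would by chance, and 1512 fell in both where 333 would. In opposite directions past both thresholds was 1 gene.

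**Figure D2:**
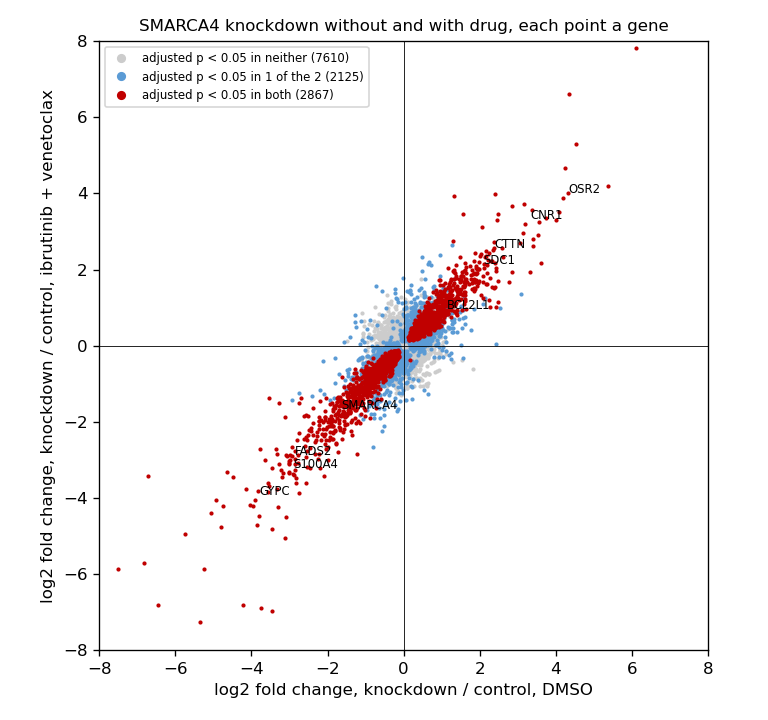
Log2 fold change of SMARCA4 knockdown against control in DMSO (x axis) and under ibrutinib plus venetoclax (y axis), each point 1 of 12602 genes, coloured by whether it passed adjusted p 0.05 in neither, 1 or both comparisons. The points lie along the diagonal, with Pearson r = 0.861 across genes.

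Drug in control cells asks what ibrutinib plus venetoclax changes with SMARCA4 present. CHAC1, a glutathione-degrading enzyme of the ATF4 response, rose by 1.53 (SE 0.14, adjusted p = 1.19e-08) and SESN2, which encodes sestrin 2, by 0.81 (SE 0.07). The immediate early transcription factor gene EGR1 fell by 2.08 (SE 0.34, adjusted p = 0.000268), the G-protein regulator RGS2 fell by 1.17 (SE 0.10) and IER2 fell by 1.17 (SE 0.19). EGR1 climbed with the replicate number in control DMSO libraries, at 55.5, 126 and 150 CPM, against 24.2, 35.3 and 18.6 CPM under drug, so its fall differs in size between replicates. The largest rises named by the rule were in short noncoding RNAs: RN7SK, the 7SK RNA that restrains transcription elongation, by 3.23 (SE 0.19), and SCARNA2, a small Cajal body RNA, by 2.69 (SE 0.13). For each of these genes the 3 drug libraries did not overlap the 3 DMSO libraries. In all, 163 genes passed, 93 higher and 70 lower, of which 25 rose and 20 fell by at least 2-fold. With library totals alone the split was 74 higher and 85 lower, and without control_IbrVen replicate 1, the library assigned by elimination, 106 genes passed.

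Cholesterol synthesis and stress genes rose as lists in control cells. Of 27 cholesterol and fatty acid synthesis genes, 9 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 9.71e-19, and adjusted p = 0.000869 with an estimated correlation). They included the desaturase gene SCD at 0.74 (SE 0.07), the squalene synthase gene FDFT1 at 0.72 (SE 0.07) and SREBF2, which encodes the transcription factor SREBP2, at 0.48 (SE 0.06). Of 31 ATF4 and amino acid stress genes, 7 rose and 0 fell (16 and 0 adjusted over the list alone; camera adjusted p = 1.19e-14, and adjusted p = 0.00259 with an estimated correlation), including the serine synthesis gene PSAT1 at 0.64 (SE 0.10). Of 21 ER chaperone and unfolded protein response genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 6.82e-06, and adjusted p = 0.00584 with an estimated correlation), including XBP1 at 0.49 (SE 0.08). XBP1 was also the 1 of 10 plasma cell genes that rose (2 higher adjusted over the list alone; camera adjusted p = 0.000751, and adjusted p = 0.0275 with an estimated correlation).

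Early response genes fell in control cells. Of 15 AP-1 and immediate early genes, 6 fell and 0 rose (9 and 0 adjusted over the list alone; camera adjusted p = 6.82e-06, but adjusted p = 0.173 with an estimated correlation), including JUNB with -0.72 (SE 0.12). Of 18 B cell receptor and NF-kB target genes, 5 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.0258, but adjusted p = 0.306 with an estimated correlation), including RGS1 with -1.31 (SE 0.18). EGR1 belongs to both lists. Of 28 G2/M genes, 0 passed over all genes and 1 fell adjusted over the list alone (camera adjusted p = 0.0258, but adjusted p = 0.0914 with an estimated correlation). The NF-kB and G2/M list calls each ended without control_DMSO replicate 3 or control_IbrVen replicate 2, with adjusted p of up to 0.134 and 0.0887.

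No tested BCL2 family gene passed the threshold for the drug in control cells, and BCL2L11, BCL2A1, BCL2L10 and BOK were not tested. The list of 4 survival members was called lower (2 lower adjusted over the list alone; camera adjusted p = 0.0206, but adjusted p = 0.0925 with an estimated correlation), with BCL2 at -0.23 (SE 0.09, adjusted p = 0.286) and BCL2L2 at -1.19 (SE 0.49, adjusted p = 0.360). This call ended without control_DMSO replicate 3, control_IbrVen replicate 1 or control_IbrVen replicate 2, with adjusted p of up to 0.0828. BTK had -0.13 (SE 0.08, adjusted p = 0.630) and ATF3 0.19 (SE 0.26, adjusted p = 0.892).

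Drug in knockdown cells asks the same question with SMARCA4 reduced. CHAC1 rose by 2.07 (SE 0.14, adjusted p = 1.30e-11), the cystine transporter gene SLC7A11 by 1.12 (SE 0.14), PSAT1 by 0.91 (SE 0.09) and SESN2 by 0.90 (SE 0.07). RN7SK rose by 2.51 (SE 0.15) and SCARNA2 by 1.95 (SE 0.12). EGR1 fell by 2.24 (SE 0.33, adjusted p = 7.69e-05), IER2 fell by 1.35 (SE 0.19) and RGS2 fell by 1.11 (SE 0.10). For each of these genes the 3 drug libraries did not overlap the 3 DMSO libraries. EGR1 again climbed with the replicate number in DMSO, at 40.5, 125 and 191 CPM, against 29.1, 31.0 and 18.1 CPM under drug. In all, 162 genes passed, 93 higher and 69 lower, of which 19 rose and 12 fell by at least 2-fold. With library totals alone the split was 132 higher and 53 lower, and the count was 100 without SMARCA4kd_DMSO replicate 3 and 102 without SMARCA4kd_IbrVen replicate 1.

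Of 27 cholesterol and fatty acid synthesis genes, 15 rose and 0 fell in knockdown cells (21 and 0 adjusted over the list alone; camera adjusted p = 1.24e-27, and adjusted p = 0.000204 with an estimated correlation), including SCD at 0.83 (SE 0.07) and FDFT1 at 0.73 (SE 0.07). Of 31 ATF4 and amino acid stress genes, 13 rose and 0 fell (21 and 1 adjusted over the list alone; camera adjusted p = 8.06e-23, and adjusted p = 0.000520 with an estimated correlation). Of 21 ER chaperone genes, 3 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.000686, and adjusted p = 0.0270 with an estimated correlation), including HSPA5, which encodes the chaperone BiP, at 0.30 (SE 0.05). AP-1 and immediate early genes had 9 of 15 lower and 0 higher (10 and 1 adjusted over the list alone; camera adjusted p = 5.55e-09), including JUN with -2.70 (SE 0.40), and B cell receptor and NF-kB targets had 5 of 18 lower and 0 higher (7 and 0; 0.000126), including EGR2 with -3.67 (SE 0.57). The list calls for AP-1 and NF-kB targets each had adjusted p = 0.0772 with an estimated correlation.

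Smaller list shifts in knockdown cells held few or no called genes. The plasma cell list was called higher with 1 of 10 members up (2 adjusted over the list alone; camera adjusted p = 0.0214) and the heat shock list with 0 of 16 (5 higher adjusted over the list alone; 0.00229). The p53 target list was called lower with 0 of 22 (3 lower and 1 higher adjusted over the list alone; 0.0155). These 3 lists had adjusted p = 0.0772 with an estimated correlation. MYC and ribosome biogenesis genes were called lower with 0 of 25 by either count (camera adjusted p = 0.0125, but adjusted p = 0.274 with an estimated correlation). The plasma cell call ended without SMARCA4kd_DMSO replicate 1, SMARCA4kd_IbrVen replicate 2 or SMARCA4kd_IbrVen replicate 3 (adjusted p up to 0.126), the p53 call without SMARCA4kd_DMSO replicate 2, SMARCA4kd_IbrVen replicate 1 or SMARCA4kd_IbrVen replicate 2 (up to 0.0804), and the MYC call without SMARCA4kd_DMSO replicate 1 (0.0677).

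No tested BCL2 family gene passed for the drug in knockdown cells, and BCL2L11, BCL2A1, BCL2L10 and BOK were not tested. BCL2 had -0.23 (SE 0.08, adjusted p = 0.266), BCL2L1 -0.16 (SE 0.09, adjusted p = 0.557) and BAX -0.31 (SE 0.09, adjusted p = 0.0671). BAX passed at -0.38 (adjusted p = 0.0403) without SMARCA4kd_IbrVen replicate 2. ATF3 went from 1.55 ± 0.423 to 3.43 ± 0.892 CPM (SD, n = 3), a log2 fold change of 1.02 (SE 0.31) that did not pass (adjusted p = 0.133).

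The drug responses of control and knockdown cells, which share no libraries, correlated at Pearson r = 0.276 and Spearman's coefficient 0.214 across 12602 genes. Pearson r was 0.536 over genes with a mean log2 CPM of at least 5. Over the 255 genes past the threshold in either population Pearson r was 0.829, a set chosen for its changes. Past both thresholds, 44 genes rose in both where 0.686 would by chance, and 25 fell in both where 0.383 would. The 1 gene past both thresholds in opposite directions was RNA18S5, a row of 18S ribosomal RNA.

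**Figure D3:**
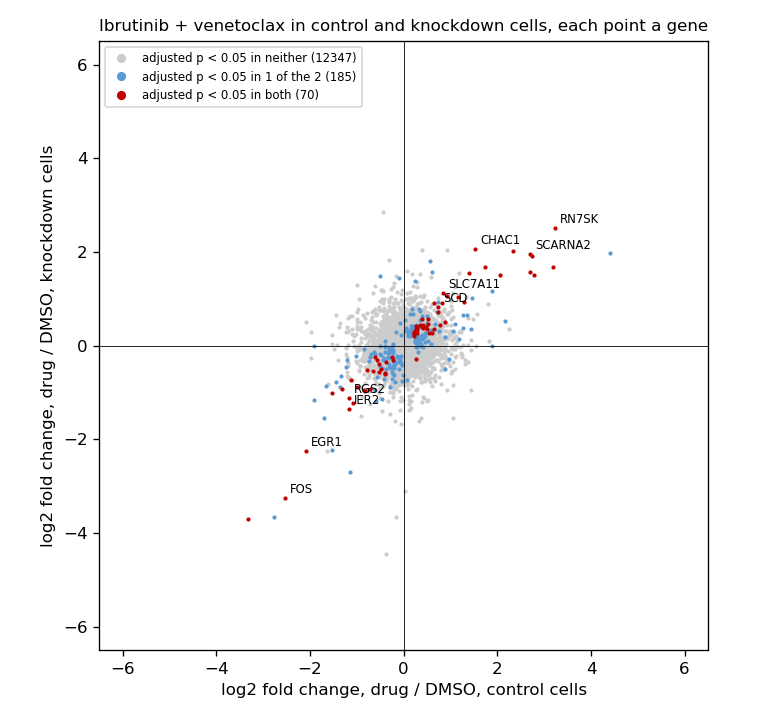
Log2 fold change of ibrutinib plus venetoclax against DMSO in control cells (x axis) and in SMARCA4 knockdown cells (y axis), each point 1 of 12602 genes, coloured by whether it passed adjusted p 0.05 in neither, 1 or both comparisons. RN7SK, SCARNA2 and CHAC1 lie high and EGR1 low in both populations.

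The interaction tests whether the drug response itself differed between knockdown and control cells. It passed for 3 genes in edgeR, against 674 at an unadjusted p under 0.05, for 4 by limma-voom, which include these 3, and for 4 by DESeq2, which include 2 of them and not RNA28S5 (adjusted p = 0.851). RNA18S5 (ENSG00000272060) had a log2 difference of -0.55 (SE 0.08, adjusted p = 0.00203) and RNA28S5, a row of 28S ribosomal RNA, of -0.79 (SE 0.15, adjusted p = 0.0480). NEAT1, a long noncoding RNA of nuclear paraspeckles, had 0.50 (SE 0.09, adjusted p = 0.0480). The drug effect on RNA18S5 was 0.27 (SE 0.06, adjusted p = 0.00834) in control cells and -0.28 (SE 0.06, adjusted p = 0.00474) in knockdown cells, on RNA28S5 0.06 (SE 0.11) and -0.73 (SE 0.11), and on NEAT1 -0.64 (SE 0.07) and -0.14 (SE 0.07). The call of RNA18S5 ended in control cells without control_DMSO replicate 1 (0.24, adjusted p = 0.0680) or control_IbrVen replicate 1 (0.25, adjusted p = 0.0849), and in knockdown cells without SMARCA4kd_IbrVen replicate 1 (-0.19, adjusted p = 0.0696). With library totals alone 2 genes were higher and 1 lower. The NEAT1 call ended without any 1 of 9 of the 12 libraries (all but control_DMSO replicate 3, SMARCA4kd_DMSO replicate 1 and SMARCA4kd_IbrVen replicate 3), with 0.45 to 0.54 and adjusted p of 0.0708 to 0.316, and with the filter at 5 CPM (adjusted p = 0.108). The RNA28S5 call ended without any 1 of 8 (all but SMARCA4kd_DMSO replicates 1 and 2, control_IbrVen replicate 1 and SMARCA4kd_IbrVen replicate 2), with -0.82 to -0.62 and adjusted p of 0.0695 to 0.191. It also ended with library totals alone (adjusted p = 0.0565) and with the filter at 5 CPM (adjusted p = 0.108).

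For the other named genes the interaction was not past the threshold. BCL2L1 had -0.15 (95% interval -0.43 to 0.12), BCL2 0.01 (-0.24 to 0.25), BBC3 -0.0044 (-0.24 to 0.23) and ATF3 0.83 (-0.0028 to 1.67, adjusted p = 0.922). The intervals, which are not adjusted for the number of genes, excluded 0 for BCL2L2, with a 2.83-fold difference (0.21 to 2.79 on the log2 scale, adjusted p = 0.914), CHAC1 at 0.53 (0.11 to 0.96, adjusted p = 0.914), RN7SK at -0.73 (-1.27 to -0.18, adjusted p = 0.836) and SCARNA2 at -0.75 (-1.13 to -0.37, adjusted p = 0.274). The 95% interval lay within 1 log2 unit either side of 0 for 9742 of 12602 genes, and for 199 of the 255 called for the drug in either population. The ATF4 and amino acid stress list was called higher (camera adjusted p = 0.0282) and the mitochondrially encoded list lower (camera adjusted p = 0.0282). Neither had a member past the threshold over all genes, 1 mitochondrial gene was lower adjusted over the list alone, and both had adjusted p = 0.588 with an estimated correlation. The ATF4 call ended without control_DMSO replicate 3, SMARCA4kd_DMSO replicate 3, control_IbrVen replicate 1, control_IbrVen replicate 2 or SMARCA4kd_IbrVen replicate 1 (adjusted p up to 0.181). The mitochondrial call ended without 7 of the 12 libraries: control_DMSO replicates 2 and 3, SMARCA4kd_DMSO replicate 3, control_IbrVen replicates 2 and 3, and SMARCA4kd_IbrVen replicates 1 and 3 (up to 0.405).

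**Figure D4:**
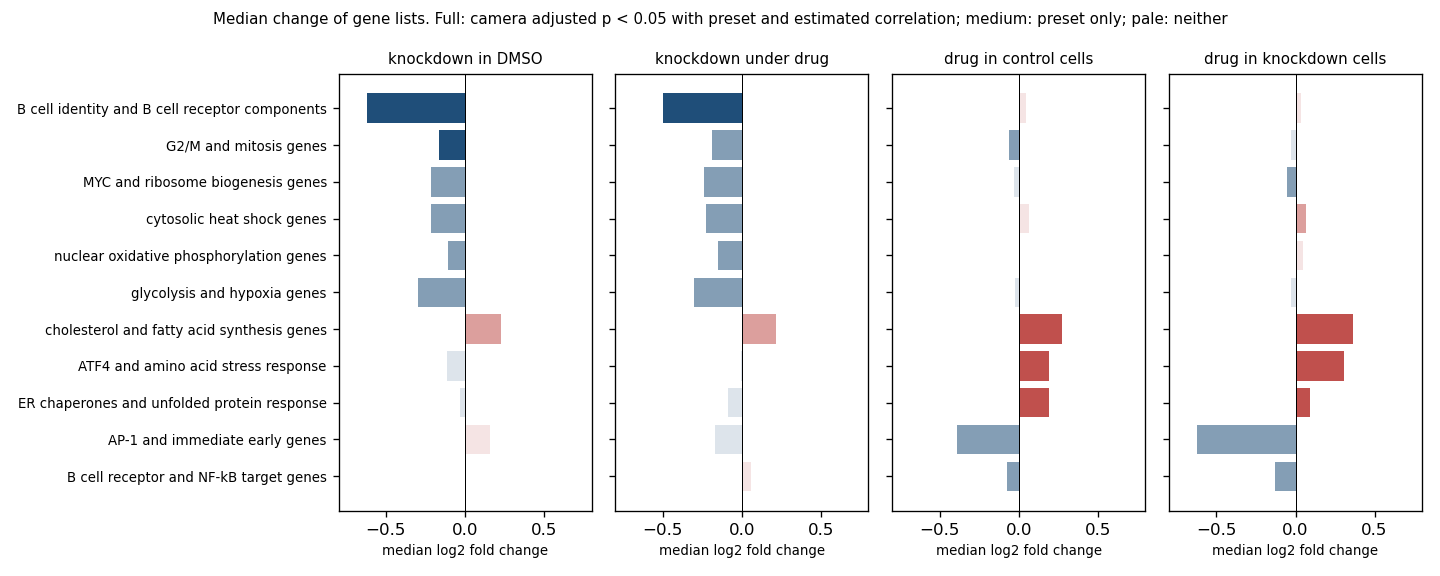
Median log2 fold change (x axis) of 11 gene lists in 4 comparisons, as bars from 0, with colour depth for a camera adjusted p under 0.05 with both the preset and an estimated correlation, with the preset alone, or with neither. B cell identity genes fell in both knockdown comparisons, and cholesterol, ATF4 and ER chaperone genes rose in both drug comparisons.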

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

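The tests of ribosomal RNA beside RN7SK, of the shRNA vector, of NEAT1 with the ribosomal RNA rows out, and the count of other splits were chosen only after the result was seen.

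RN7SK rose under drug by 3.23 on the log2 scale in control and 2.51 in knockdown cells, and SCARNA2 by 2.69 and 1.95, although the kit primes on poly(A) tails that these RNAs lack. More RNA without a tail in the drug libraries would raise the 46 tested HIST genes, most of whose mRNAs lack one, by over 1. Their median was 0.26 (95% bootstrap interval 0.17 to 0.48) in control and -0.13 (-0.20 to 0.0036) in knockdown cells. Of them, 5 rose and 0 fell in control cells, and 2 rose and 2 fell in knockdown cells. These HIST rows passed the count filter with a kit that primes on tails, and whether their reads had a tail is unknown. The HIST medians therefore cannot exclude more RNA without a tail. More ribosomal RNA reads would raise RNA18S5 and RNA28S5 alike, but the highest of their drug effects was 0.27 (SE 0.06). Over 115 small noncoding RNA genes the median was 0.21 (0.14 to 0.28) in control and 0.14 (0.09 to 0.28) in knockdown cells. This set holds RN7SK but not SCARNA2, whose identifier did not match those gene types. The medians argue against a rise of every such row by over 1, but both intervals lie above 0. Many rows are named as pseudogenes or have no symbol, so the median cannot exclude a rise of the functional small noncoding RNAs. Of the other 114, 8 rose and 0 fell in control cells, and 4 rose and 0 fell in knockdown cells, among them RNU6ATAC and RNU4-2 in both, so the rise is not particular to RN7SK and SCARNA2, and a drug effect on the making, tailing or stability of some small noncoding RNAs stays open and untested.

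MIR30A rose with the SMARCA4 shRNA by 3.13 in DMSO and 2.97 under drug. Higher transcription of its host gene cannot be told apart from other causes, because the host transcript LINC00472 was not among the genes tested and only MIR30A's own 3.13 is at hand. Reads from a microRNA-30-based shRNA vector would differ by shRNA and not by drug, and the larger of the drug effects on MIR30A was 0.35 (SE 0.13, adjusted p = 0.286), as that source would give. An effect of SMARCA4 loss on MIR30A predicts the same value. The construct and the knockdown coincide in every library and the vector is not given in the sources used here, so both stay open.

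The drug effect on ribosomal RNA differed between populations: the interaction, which tests that difference, was -0.55 for RNA18S5 and -0.79 for RNA28S5, and 0.50 for NEAT1. A single library is argued against as the whole cause for RNA18S5, since without SMARCA4kd_IbrVen replicate 1, which had the lowest level, its interaction was -0.46 (SE 0.07, adjusted p = 0.00154). The weight of ribosomal RNA in the scaling is argued against as the whole of NEAT1's difference: with library totals as scaling, where those rows carry weight, it was 0.56 (SE 0.0954) before and 0.50 (SE 0.0939) after 5 of them were taken out, a step that moved the median gene by -0.06, but its call ended (adjusted p = 0.133), as it did with TMM at 0.50 before and after (adjusted p = 0.134), where the adjustment no longer held the smaller p-values of RNA18S5 and RNA28S5. Of 60 drawn splits, of 200 possible, 5 gave as many as the 3 interaction genes, the highest other 82, and chance is neither excluded nor shown by that count. The splits with 82, 66, 61 and 25 genes kept the real drug labels in 1 population and exchanged most in the other. They carry the drug response itself and are no guide to chance. The real split aside, the rest gave 0 or 1, but each mixes drug and DMSO libraries in 1 or both populations. A drug response then widens the spread, so they are no guide either. The interactions of RN7SK and SCARNA2, not past the threshold, were also negative, at -0.73 (95% interval -1.27 to -0.18) and -0.75 (-1.13 to -0.37). The HIST median under drug was 0.26 in control and -0.13 in knockdown cells, and that of small noncoding RNAs 0.21 and 0.14. A difference in RNA quality or capture between the groups stays open beside a biological one.

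The ATF4 and amino acid stress list was called for the interaction with a median of 0.10 (camera adjusted p = 0.0282), but 0 of its 31 members passed, it had adjusted p = 0.588 with an estimated correlation and 0.309 with fry, and 5 of 12 fits without 1 library ended it. The mitochondrially encoded list was called with a median of -0.15 (camera adjusted p = 0.0282), but it had adjusted p = 0.588 with an estimated correlation, 0.321 with fry and 0.0873 with library totals alone, and 7 of 12 fits without 1 library ended it.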

How the results depend on the processing

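The fits with the ribosomal RNA rows out, with the deepest library thinned and with the replicate block in the DMSO libraries alone, and the leave-outs for the 2 correlations across genes, were chosen only after the data were seen. SMARCA4 kept its direction and call in all 19 alternatives in DMSO (-1.80 to -1.71) and all 17 under drug (-1.84 to -1.72). The counts for the knockdown comparisons stayed within 1.5 times in every alternative but the 2-fold minimum, with 3218 to 3528 genes in DMSO and 3312 to 3548 under drug without 1 library. With a 2-fold minimum, which counts fewer genes by construction, 756 genes passed for knockdown in DMSO, 45 for the drug in control cells, 31 for the drug in knockdown cells, 807 for knockdown under drug and 0 for the interaction. Leaving out 1 library gave 106 to 160 genes for the drug in control cells (106 without control_IbrVen replicate 1), 100 to 164 in knockdown cells (100 without SMARCA4kd_DMSO replicate 3) and 1 to 3 for the interaction. Without control_IbrVen replicate 1, the library assigned by elimination, knockdown under drug gave 3476 genes and the interaction 2. The interaction gave 1 gene with the stricter filter and 0 without the ribosomal RNA rows under either scaling, 2 of which were among the 3. In DMSO, where replicate numbers pair the libraries, the replicate block of those libraries gave 3916 genes (3754 with the deepest library thinned) and changed no other call named here than that of MCL1. Elsewhere the samples share only a number: of all 18 same-number pairs 6 correlated above 0.1, range -0.399 to 0.337, and 12 of 36 best matches had the same number. With the numbers as a block over all libraries, counts were 3822, 150, 147, 3827 and 2 in the order knockdown in DMSO, drug in control, drug in knockdown cells, knockdown under drug and interaction, where NEAT1 had adjusted p = 0.0628. The correlation of the drug responses was 0.536 over genes with a mean log2 CPM of at least 5 and 0.223 to 0.257 without 1 library, and that of the knockdown responses 0.930 and 0.828 to 0.840. Named genes kept their direction wherever they passed, and of their values 2250 of 2346, 962 of 1015, 845 of 895, 2016 of 2119 and 381 of 408 kept their side of the threshold, in the same order.

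Of 37 list calls, 10 held with an estimated correlation and 27 did not, and 28 held in every other alternative. For 35 of the 37 the estimated correlation gave the highest adjusted p of any alternative. The calls it ended had these adjusted p. For knockdown in DMSO: heat shock 0.0670, MYC and ribosome biogenesis 0.0674, oxidative phosphorylation 0.232, glycolysis 0.119, cholesterol 0.154, T and NK markers 0.0721. For knockdown under drug: heat shock, MYC, glycolysis, cholesterol and T and NK markers 0.0789 each, G2/M 0.0695, ribosomal proteins 0.594, mitochondrially encoded 0.386, oxidative phosphorylation 0.345. For the drug in control cells: BCL2 survival members 0.0925, NF-kB targets 0.306, AP-1 0.173, G2/M 0.0914. For the drug in knockdown cells: plasma cell, NF-kB, AP-1, heat shock and p53 lists 0.0772 each, MYC 0.274. For the interaction: ATF4 and mitochondrially encoded 0.588 each. With fry, MYC for the drug in knockdown cells had 0.0529, and the interaction lists ATF4 0.309 and mitochondrially encoded 0.321. With library totals alone MYC for the drug in knockdown cells had 0.058 and the mitochondrial interaction 0.0873. With the block, ribosomal proteins for knockdown under drug had 0.0571. Without 1 library the adjusted p spanned 0.00399 to 0.181 for the ATF4 interaction, 0.00248 to 0.405 for the mitochondrial interaction, 0.00722 to 0.134 for NF-kB targets, 0.00722 to 0.0828 for BCL2 survival members and 0.0266 to 0.0887 for G2/M with the drug in control cells. It spanned 0.00919 to 0.0677 for MYC, 0.00267 to 0.0804 for p53 and 0.00902 to 0.126 for plasma cell genes with the drug in knockdown cells, and 0.00225 to 0.168 for ribosomal proteins with knockdown under drug. Except where construction is named above, the cause was not tested. Of the smallest simulated changes, 12% were recovered for the interaction, 24% for the drug in control cells and 54% for knockdown in DMSO. Each run changed its own random draw of genes, so these shares also vary by draw. No simulation varied depth.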

Other observations

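The count of other splits of the libraries was chosen only after the result was seen.

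Further lists had members past the threshold for SMARCA4 knockdown in DMSO without a list call, in a comparison where 31.3% of all genes tested passed, so their counts alone do not mark a list as changed. Among 25 SWI/SNF subunits tested, 7 rose and 3 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.296): the alternative ATPase gene SMARCA2 fell by 0.51 (SE 0.07), while SMARCD3 rose by 0.95 (SE 0.12) and BCL7A by 0.46 (SE 0.05). Among 8 mantle cell lymphoma marker genes, 4 fell and 1 rose, also adjusted over the list alone (0.503): the transcription factor gene SOX11 rose by 0.92 (SE 0.05), the chemokine receptor gene CCR7 fell by 1.38 (SE 0.10) and the cyclin D1 gene CCND1 fell by 0.33 (SE 0.06). Of 10 plasma cell genes, 2 rose and 3 fell, also adjusted over the list alone (0.935): PRDM1, which encodes the plasma cell regulator BLIMP1, rose by 1.22 (SE 0.13) beside SDC1, while CD38 fell by 1.39 (SE 0.21). Of 17 type I interferon genes, 4 fell and 0 rose (8 and 1 adjusted over the list alone; 0.148), with ISG20 at -1.28 (SE 0.14) and MX2 at -2.57 (SE 0.35). Of 13 HLA class II genes, 5 rose and 1 fell (5 and 2 adjusted over the list alone; 0.197): the class II transactivator gene CIITA rose by 0.54 (SE 0.06) and the invariant chain gene CD74 fell by 0.34 (SE 0.05).

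Of 22 p53 targets, 6 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.148), with BTG2 at 1.19 (SE 0.12) and SESN1 at 0.81 (SE 0.13). Of 31 ATF4 and amino acid stress genes, 3 rose and 12 fell (4 and 12 adjusted over the list alone; 0.0924): TRIB3 fell by 1.35 (SE 0.14) and SHMT2 fell by 0.52 (SE 0.06), while the amino acid transporter gene SLC7A5 rose by 0.86 (SE 0.06). Of 18 autophagy and lysosome genes, 3 rose and 4 fell (4 and 6 adjusted over the list alone; 0.895), with the autophagy genes ULK1 at 0.89 (SE 0.07) and GABARAPL1 at 2.27 (SE 0.22). Of 12 NRF2 targets, 1 rose and 5 fell (3 and 5 adjusted over the list alone; 0.251). Of 30 G1/S and DNA replication genes, 1 rose and 9 fell, also adjusted over the list alone (0.0614). Of 17 caspase, death receptor and IAP genes, 5 rose and 3 fell (7 and 4 adjusted over the list alone; 0.503), with BIRC3 at 0.56 (SE 0.08). The NF-kB, AP-1, ER chaperone, ribosomal protein and mitochondrially encoded lists were not called for knockdown in DMSO either (0.503, 0.503, 0.440, 0.158 and 0.124). All these calls are by camera. With fry, lists that moved lower were NRF2 (adjusted p = 4.55e-05), interferon (0.000644), ATF4 (0.000775), G1/S (0.000866), ER chaperone (0.0183) and mitochondrially encoded (0.0268). The p53 (0.000461) and HLA class II (0.00571) lists moved higher with fry.

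For the 4 comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In each, 1 of the 10 splits, the real one, gave as many genes as the real count. Every other split mixes libraries of the 2 groups compared in each set of 3. A real difference then widens the spread within a set, so low counts there are no guide to chance. For knockdown in DMSO the real count was 3940 and the highest of the other splits 0 (also among the 3 others that part all 3 same-number pairs), for knockdown under drug 3919 and 0, for the drug in control cells 163 and 0, and for the drug in knockdown cells 162 and 15.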
